A study of Mus musculus with 2 samples.

How the data were processed

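Tumors from mice of strain C57BL/6J were profiled as 2 single-cell libraries, 1 of wild-type mice (WT) and 1 of mice with a hepatocyte knockout of Fabp5 (hKO). Per the labels, littermates aged 6 to 8 weeks received tamoxifen 5 times, 100 mg/kg every 3 days after 16 h of fasting, and the diet followed 2 weeks later for 15 months. Each library is a pool of 2 to 3 tumors digested with collagenase for 1 h at 37 °C and passed through a 40 µm filter. Group and treatment were read from the labels.

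The counts are raw UMI counts per gene and barcode, deposited as whole numbers without normalization, and per the file headers Cell Ranger 7.1.0 made them. The other columns, which name genes and barcodes, were deposited unchanged as the row and column names of those counts. Per the submitters' processing notes, Cell Ranger, R 3.0 and Seurat 3 were used with genome build mm9, and the annotation release is not given in the sources used here. The lowest total of a barcode was 500 UMIs in both libraries, so these are called cells. Of 32285 feature IDs, identical in both libraries, 32158 matched the GENCODE M21 annotation, which is for another build than the one noted. No coordinates were used, and gene symbols are those of the counts. There are 78 symbols shared by more than 1 ID. Mx1, in the interferon response list, had no feature under that symbol.

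Barcodes were kept with at least 200 genes, at least 500 UMIs and at most 25% mitochondrial UMIs. In WT 2645 barcodes were over the mitochondrial limit and 2224 had under 200 genes, and in hKO 6864 and 593, leaving 9853 and 11451. Doublets were scored per library with Scrublet, at an expected rate of 0.008 per 1000 barcodes. Its own threshold called 4.00% in WT, and these 394 cells were removed. In hKO it called 0.0262%, under the fixed limit of 0.5%, so the top 9.16% of scores, the expected rate, were removed instead (1049 cells). This left 9459 WT and 10402 hKO cells with 48316788 and 48298752 UMIs. Median genes per cell were 1719 and 1614, and the median mitochondrial share was 6.95% and 10.0%.

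Both libraries were then clustered together without integration: counts per 10000, log(1 + x), 2000 variable genes chosen per library (mitochondrial, ribosomal-protein and immunoglobulin genes and Fabp5 left out), scaled values capped at 10, 30 principal components, 15 neighbors and Leiden resolution 1.0 with seed 1. A cluster was named for the type, of 16 with fixed markers, whose markers had the highest mean log2 ratio over the mean of the other clusters (pseudocount 20 CPM, counts per 1000000 UMIs), with at least 3 markers raised. A marker was raised at 30 CPM or more and a log2 ratio of at least 1. A cluster stayed unnamed where at least 50% of the markers of an unrelated type were raised, where its 10 leading genes held more markers of another type, or where its depth was under 33.3% of the library median and none of its own markers were among them. Cluster 21, the WT hepatocyte-like cells, stood at 34.1% without such a marker, and hKO cluster 9 at 37.9%. Of 31 clusters 3 stayed unnamed: 13 with T and macrophage markers (229 WT and 489 hKO cells), 25 with cholangiocyte and hepatocyte markers (200 and 34), and 31 with erythroid and B markers (37 and 1). Class names end in -like because markers alone gave them. With 1 library per group, a cluster that comes mostly from 1 library may reflect that library and not a cell type. Macrophage-like and T-like cells were clustered again on their own (resolution 0.5) to name subsets.

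UMIs were summed per class and library and scaled to CPM of all UMIs of the class. Classes with at least 100 cells in each library were compared, 11 in all. The log2 ratio is hKO over WT with its exact conditional binomial 95% interval. Intervals are exact Poisson for CPM and Clopper-Pearson for shares, and they cover counting error only. A count of 0 was set to a floor of 3 counts over the class, and a ratio against it is a bound. With 1 library per group no test, p-value or SE was computed, and the comparison is WT against hKO in each class.

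Named genes follow a rule. A gene passes with at least 50 CPM in a library, a log2 ratio of at least 1 in size and an interval that excludes 0. Mitochondrial, ribosomal-protein, hemoglobin, immunoglobulin and T-cell-receptor segment genes and numbered predicted genes are left out. A gene that another class of the same library holds at over 10 times the level is set aside as free RNA. The 10 highest and 10 lowest genes are named in hepatocyte-like, macrophage-like and T-like cells, and 3 each way in the other 8 classes. Fabp5 is named in each class, and 2 to 4 members with the largest ratios from each of 31 fixed lists (472 genes) in the classes the list is about. Some genes that this rule names are not reported here. The lists cover lipid handling, cholesterol synthesis, ferroptosis, NRF2 targets, tumor and mature hepatocyte genes, acute phase, hypoxia, stress, interferon, antigen presentation, macrophage and T cell states, proliferation, matrix, angiogenesis, chemokines, free hepatocyte RNA and sex. A list needs 4 members with at least 20 UMIs in a library, and its median log2 ratio is placed among 10000 random lists matched on mean expression in 20 bins. For shares of cells with a UMI, each cell was thinned without replacement to 1000 UMIs and shallower cells were left out.

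The rule of size was tested on simulated data, with counts drawn from the mean profile of both libraries at their real totals and some genes changed by a known fold. At 1.5-fold 0% passed in hepatocyte-like, macrophage-like and T-like cells. At 2-fold 34%, 48% and 42% passed, at 3-fold 100% in each, and at 4-fold 96%, 98% and 98%. Of 2038, 3067 and 3327 unchanged genes 0 passed. The simulation held counting error only, with no difference between pools, in cluster make-up or in free RNA, and no free RNA step. It therefore gives no rate of false calls between 2 pools.

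The 17 alternatives chosen before the data were examined change the mitochondrial limit, cell minimums, doublet removal, clustering, scaling, free RNA, floor, size, share denominator, list minimum and thinning depth, and 3 more were added after the data were seen. Subtracting free RNA took each library's mean profile times a share set from the free hepatocyte list in T-like cells, 32.6% of UMIs in WT and 42.7% in hKO. That profile was summed over the kept cells, not over empty droplets, so the step also removes RNA that cells made themselves. With it 20 genes were higher and 177 lower in B-like cells, in place of 96 and 15. A change under this setting therefore does not show that a result came from free RNA. Analyses used Python 3.11.15, scanpy 1.11.5 with its Scrublet, anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.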

Results

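Single-cell RNA was measured in liver tumors of C57BL/6J mice by droplet-based 10x Genomics 3′ sequencing, which counts each captured transcript once by its unique molecular identifier (UMI). There were 2 libraries, 1 per group. The WT library came from tumors of wild-type mice, and the hKO library from tumors of mice lacking Fabp5, a fatty acid binding protein, in hepatocytes after tamoxifen. Each library pooled 2 to 3 hepatocellular carcinomas taken after 15 months on a choline-deficient high-fat diet, which produces fatty liver disease and tumors. The design asks whether losing FABP5 in hepatocytes goes with differences in tumor cells and in the surrounding immune cells. There are no replicates, so no test was possible: each value describes these 2 pools, and each interval covers counting error only.

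The WT library held 14289 barcodes with 58772330 UMIs, and the hKO library 18657 barcodes with 68010317 UMIs. After filtering and doublet removal, 9459 WT cells (median 3822 UMIs) and 10402 hKO cells (median 3642.5 UMIs) were kept. The share of barcodes over the mitochondrial limit was 18.5% in WT and 36.8% in hKO. Hepatocyte transcripts outside hepatocytes differed too: the fixed list of 12 abundant hepatocyte genes made up 0.228% of UMIs in WT T-like cells and 0.575% in hKO T-like cells. Hemoglobin made up 8.15% of UMIs in WT and 1.65% in hKO over all barcodes, before filtering. Of these hemoglobin UMIs, 3407495 in WT and 541947 in hKO lay in barcodes with under 200 genes, which were removed. Both libraries carried Y-linked transcripts (Ddx3y 5718 and 5817 UMIs) and almost no Xist (7 and 8 UMIs), so the mice of both pools appeared male. The sex-linked list had a median log2 ratio, hKO over WT, of −0.02 in macrophage-like and −0.18 in T-like cells.

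Of 31 clusters, 28 were named by fixed markers and fell into 14 cell classes. Endothelial-like cells took a smaller part of the hKO library, 5.32% (95% Clopper-Pearson interval 4.89 to 5.76) against 15.6% (14.8 to 16.3) in WT, a log2 ratio of −1.55. Hepatocyte-like cells took a larger part, 10.6% (10.0 to 11.2) against 3.69% (3.32 to 4.09), a log2 ratio of 1.52. Plasmacytoid dendritic-like cells, the main makers of type I interferon, were 8.97% (8.43 to 9.53) of hKO and 3.18% (2.84 to 3.56) of WT cells. Monocyte-like cells were also more frequent in hKO, 11.9% against 7.09%, as were conventional dendritic-like cells, 6.00% against 4.88%. Neutrophil-like cells were 2.53% of hKO and 5.28% of WT cells, NK or innate lymphoid-like cells 2.70% and 4.26%, and erythroid-like cells 1.60% and 3.18%. Macrophage-like cells (16.5% and 17.8%), T-like cells (16.1% and 15.2%) and B-like cells (12.3% and 13.7%) differed less. Plasma-like cells numbered 3 in hKO and 61 in WT, stellate or fibroblast-like cells 17 and 35, and mast or basophil-like cells 28 and 32. The Plasma-like counts followed doublet removal: they were 46 in hKO and 74 in WT with doublets kept. With doublets removed only by the caller's own threshold they were 58 and 74. Immune classes together made up 77.3% of hKO and 72.3% of WT cells. Among kept immune cells, plasmacytoid dendritic-like cells were 11.6% of hKO and 4.40% of WT cells and macrophage-like cells 21.4% and 24.6%. Shares may also follow dissociation, which was not tested. They changed with other mitochondrial limits, at which cells were also clustered and named again. At a limit of 10% the hepatocyte-like log2 ratio was −0.11, or 0.39 with the main clusters kept, and the macrophage-like one 0.78. At 50% the hepatocyte-like one was 5.29, with 64 WT cells so named in place of 349. The conventional dendritic-like one was −0.18 there and the stellate or fibroblast-like one 0.19.

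**Figure D1:**
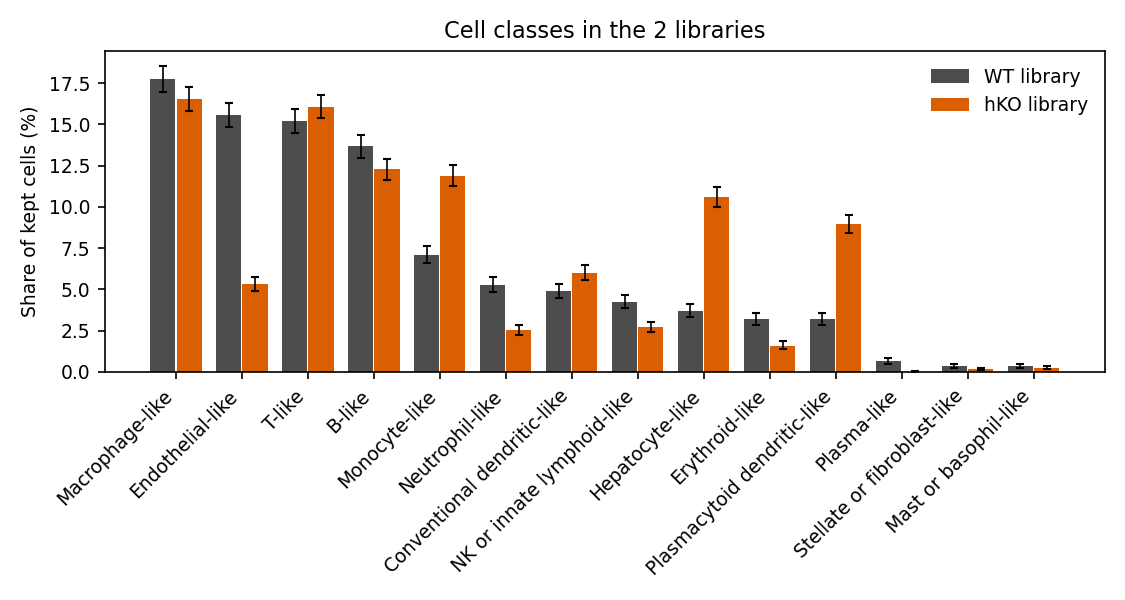
Share of kept cells (percent, vertical axis) for each named cell class (horizontal axis) in the WT and hKO libraries, with 95% Clopper-Pearson intervals as error bars. Endothelial-like cells stand at 15.6% in WT and 5.32% in hKO, hepatocyte-like cells at 3.69% and 10.6%, and plasmacytoid dendritic-like cells at 3.18% and 8.97%.

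Fabp5 (ENSMUSG00000027533), the targeted gene, was lower in the hepatocyte-like cells of the hKO library: 51 UMIs, or 13.8 CPM (counts per 1000000 UMIs of the class, exact Poisson interval 10.3 to 18.2), against 79 UMIs, or 100.0 (79.2 to 124.6), in WT. The log2 ratio was −2.85 (95% counting interval −3.39 to −2.33). Which exons were deleted is not given in the sources used here, and a 3′ tag outside the deleted part checks nothing, so these UMIs say nothing of the protein. Hepatocyte-like cells lay in different clusters in the libraries, cluster 21 in WT and clusters 9 and 22 in hKO. With doublets kept, stricter cell minimums, a 10% mitochondrial limit or Leiden resolution 2.0, the log2 ratio lay between −1.34 and −1.02, and WT hepatocyte-like cells held 3133567 to 3887559 UMIs (median 1944 to 5468 per cell) in place of 790130 (median 1300). The main comparison left out unnamed cluster 25, with cholangiocyte and hepatocyte markers, whose 200 WT cells held 3990628 UMIs. At resolution 2.0 WT hepatocyte-like cells numbered 471 in place of 349, and a cholangiocyte-like class of 82 WT cells appeared. In WT these classes held 3633153 and 1143168 UMIs there. The hKO cholangiocyte-like class of that setting had 34 cells and 398922 UMIs, the same counts as hKO cluster 25. These totals go with cells of cluster 25 entering these classes, but single cells were not traced. Thinned to 1000 UMIs per cell, 11.7% of WT (7.79 to 16.7) and 1.63% of hKO hepatocyte-like cells (0.869 to 2.77) had a Fabp5 UMI. Of these cells 127 in WT and 304 in hKO were too shallow to enter. The unthinned shares were 16.9% and 3.17%, at median depths of 1300 and 1506 UMIs. In T-like cells, taken as background, 0.356% of WT and 0.610% of hKO cells had one, at median depths of 3684.5 and 3741 UMIs.

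Outside hepatocytes, Fabp5 did not move one way. In neutrophil-like cells it was lower in hKO, 22.8 against 64.3 CPM (log2 −1.49, −2.37 to −0.69). Macrophage-like cells held 33.2 in hKO and 27.8 in WT (log2 0.25, −0.04 to 0.55), endothelial-like cells 23.5 and 17.0 (log2 0.47, 0.03 to 0.90), and T-like cells 8.82 and 4.47 (log2 0.98, 0.32 to 1.68). The T-like value was −0.10 at a mitochondrial limit of 50% and 2.34 with free RNA subtracted, and the macrophage-like one 1.02 at a limit of 10%. Intervals included 0 in monocyte-like (log2 −0.46), conventional dendritic-like (0.53), B-like (1.22), NK or innate lymphoid-like (−0.37) and plasmacytoid dendritic-like cells (0.20). Erythroid-like cells had 6 Fabp5 UMIs in WT and 0 in hKO, where a count of 0 allows up to 3 UMIs, and no ratio is given.

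**Figure D2:**
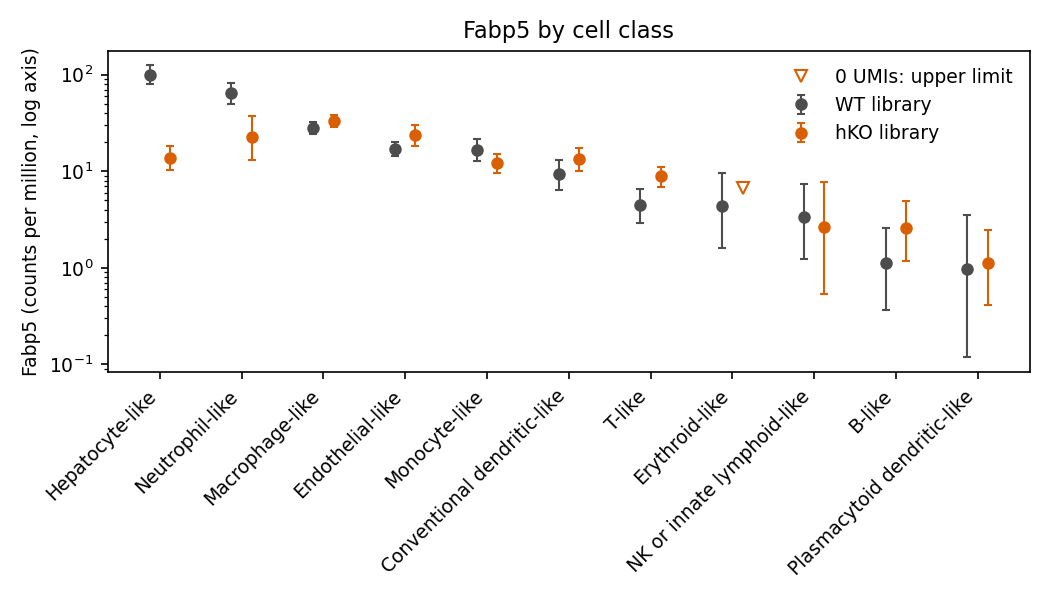
Fabp5 in CPM (vertical log axis) for each compared cell class (horizontal axis) in the WT and hKO libraries, with exact Poisson 95% intervals as error bars. Hepatocyte-like cells hold 100.0 in WT and 13.8 in hKO, macrophage-like cells 27.8 and 33.2, and the open triangle is the upper limit for erythroid-like cells of hKO, which had 0 UMIs.

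A gene passed the rule of size in a class with at least 50 CPM in a library, a log2 ratio of at least 1 in size and a counting interval that excludes 0. Genes named as examples of a list are those with the largest ratios and need not pass this rule. The counts that follow describe these 2 libraries. CPM values carry a shift between the libraries: the median log2 ratio over genes at the floor in both was −0.41 in hepatocyte-like, −0.05 in macrophage-like, −0.16 in T-like and −0.47 in erythroid-like cells, and between −0.16 and −0.09 in the other classes. Members of near-identical families (Ugt2b, Cyp2c, Cyp4a, Mup, Saa, Gsta and Hspa1 genes) share sequence, so how reads split among them is uncertain.

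In hepatocyte-like cells, genes with large differences had varied functions. Afp, the fetal albumin used as a liver tumor marker, stood at 275.9 CPM in WT and 4.61 in hKO (log2 −5.90, −6.71 to −5.19). Gpc3, a fetal proteoglycan of liver cancer, was also lower (46 and 5 UMIs, log2 −5.43), as was the hydroxysteroid dehydrogenase Akr1c18 (852 and 14 UMIs, log2 −8.15). Slc7a11, which imports cystine for glutathione synthesis, was higher in hKO (1 and 713 UMIs, log2 7.25, 4.77 to 12.56). That ratio was much smaller under the settings named for Fabp5, as given below. In all, 574 genes were higher and 892 lower in hKO, with 12 and 36 more set aside as free RNA. The higher genes were 39.2% of those that passed. They were 51.0% (870 higher, 836 lower) with abundant gene kinds left out of the total, 65.7% (892 and 466) with median scaling, and 54.4% (551 and 462) without hKO cluster 9, led by Cyp2a5, Ugt2b5 and Mup20 (median 1379 UMIs, against 1300 in WT cluster 21). Under the settings named for Fabp5 they were 18.7% (337 and 1466) with doublets kept, 18.8% (344 and 1482) at resolution 2.0, 19.4% (359 and 1495) with stricter cell minimums and 26.8% (382 and 1042) at the 10% limit. Most genes that passed in the main setting, 1466 in all, did not pass the same way there. Those that did were 621 with doublets kept, 638 at resolution 2.0, 601 with stricter cell minimums and 403 at the 10% limit.

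The other genes highest in hKO were the glucuronosyltransferase Ugt2b35 (log2 7.39), the adhesion gene Cdh2 (6.28), the cytochromes Cyp2c29 (6.22) and Cyp4a12a (5.96), the carboxylesterase Ces1g (6.18), the nucleotide sugar transporter Slc35d1 (6.09), the retinol saturase Retsat (5.99), Cdhr5 (5.96) and the acute-phase gene Orm2 (5.91). WT counts of these genes were 6 UMIs or fewer, so their intervals are wide, from 3.47 to 11.27 for Cdhr5. Lowest in hKO, beside those above, were the inositol oxygenase Miox (76 UMIs in WT and 0 in hKO, at least 118-fold lower from a floor of 3 counts), Kazald1 (log2 −6.70, −9.02 to −5.10), Agxt, which detoxifies glyoxylate (−5.20), Rgn (−4.89), Nlrp12 (−4.86), Clmp (−4.68) and the sulfotransferase Sult2a2 (−4.53). Akr1c18 and Rgn also led WT cluster 21, and Cyp3a11, Tff3 and Cbr3, named with the lists, led the hKO clusters. Under the settings named for Fabp5, Slc7a11 lay between 0.64 and 1.33 and Cdh2 between −0.40 and −0.02, while Afp was at most −5.09.

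Several fixed gene lists had medians far from those of matched random lists in hepatocyte-like cells. Of 15 measured acute phase genes 11 passed as higher in hKO and 1 as lower, with a median log2 ratio of 2.25, above all 10000 matched random lists (percentile 100). Examples are Orm2, Saa1 (3.81), Lbp (3.80) and Saa3 (0 UMIs in WT and 149 in hKO, at least 10.6-fold higher, but under the floor of the rule). Glutathione and NRF2 targets, which protect from oxidants, had 8 of 19 higher and 1 lower (median 0.97, percentile 99.9), with the transporter Abcc4 (5.87), Gpx2 (5.52), the epoxide hydrolase Ephx1 (5.28) and Cbr3 (4.12). Fatty acid binding and uptake had 5 of 12 higher and 2 lower (median 1.19, percentile 99.2), led by the transporters Slc27a4 (3.36), Cd36 (3.14) and Slc27a5 (2.68) and the lipase Lpl (3.10). Lipogenesis had 4 of 15 higher and 1 lower (median 0.70, percentile 99.6), with Scd2 at 3.27 and Lpin1 at −3.09, but a median of 0.060 at the 10% limit. Cholesterol synthesis had 3 of 18 each way (median 0.75, percentile 99.8; Sqle 3.23), and unfolded protein response genes 5 of 14 higher and 0 lower (median 0.68, percentile 99.2; Hyou1 2.86, Creld2 2.66). The cholesterol median was −0.34 with a mitochondrial limit of 10%, −0.31 with stricter cell minimums, −0.27 with doublets kept and −0.30 at resolution 2.0, and the unfolded protein one −0.14 at that limit and −0.66 with doublets kept. The acute phase median was 0.53 at that limit. Hyou1 stood at −0.072 at that limit and −0.047 with doublets kept, and Creld2 at −0.53 with doublets kept.

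Other lists in these cells moved less or went both ways. Lipid droplet genes had 3 of 14 higher and 3 lower (median 0.53, percentile 97.2), with Fitm2 at 4.18 and Hsd17b13 at 3.06. Fatty acid oxidation had 3 of 20 higher and 5 lower (median −0.53, percentile 21.5), with the omega-hydroxylase Cyp4a10 at 4.52 and the thiolase Acaa2 at −1.94. Ferroptosis regulators had 5 of 18 higher and 2 lower (median −0.12, percentile 76.9). Among them were Slc7a11, with a much smaller ratio under the settings named for Fabp5, and the reductase Por at 4.16 (−0.072 at the 10% limit). Fetal liver and tumor genes split 3 higher and 3 lower of 12 (median −0.34, percentile 40.3): Akr1c18, Afp and Gpc3 were lower and Tff3 was higher (36 and 8262 UMIs, log2 5.62). Mature hepatocyte genes split 6 and 6 of 21 (median 0.21, percentile 92.3), with Cyp2c29, the bile acid enzyme Cyp8b1 (4.95) and Cyp3a11 (4.86). Medians were −0.18 for glycolysis and hypoxia (percentile 49.7; P4ha1 2.48, Vegfa 2.13), −0.77 for dissociation stress (7.58; Egr1 −2.77, Hspb1 1.45), 0.28 for interferon response (82.4; Bst2 1.95, Cxcl10 1.79), 0.26 for MHC class I presentation (87.8; Tap2 3.13, Tapbp 2.28) and −0.66 for proliferation (5.63; Top2a 2.56, Ccnb2 −2.28). Ccnb2 became 0.72 at the 10% limit and 0.10 with stricter cell minimums, and Hspb1 lay between −0.40 and −0.12 under the settings named for Fabp5.

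**Figure D3:**
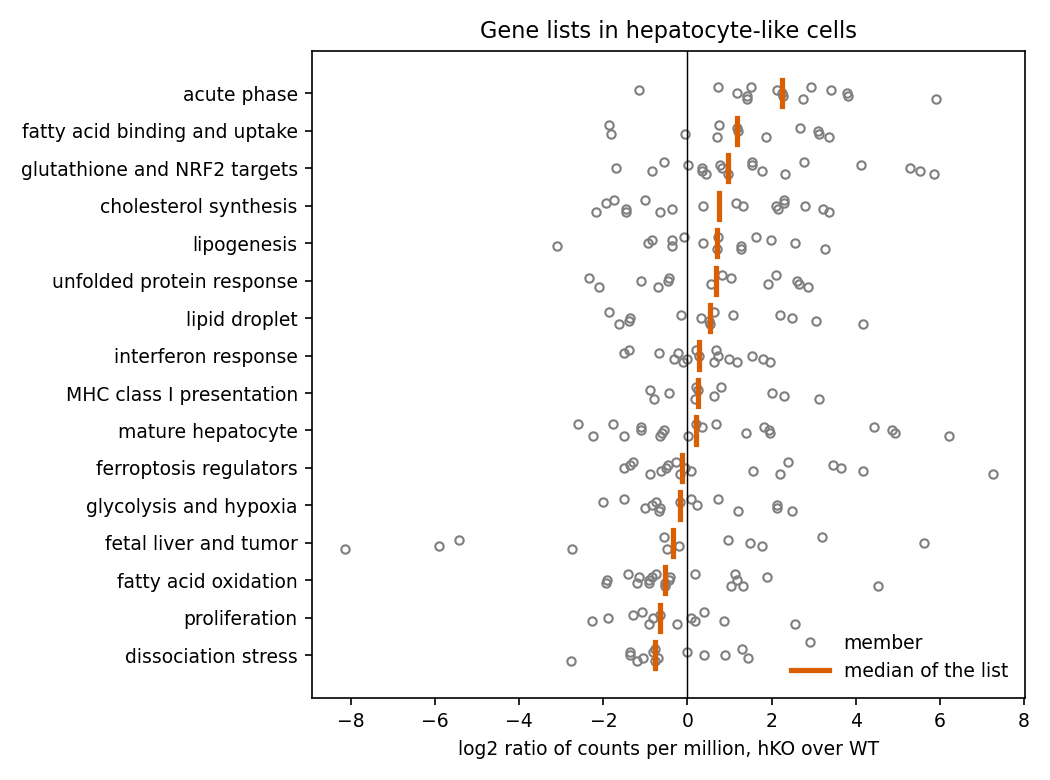
Log2 ratio of CPM, hKO over WT (horizontal axis), of each measured member of 16 fixed gene lists (vertical axis) in hepatocyte-like cells. Circles are genes and bars the median of a list, which runs from 2.25 for acute phase to −0.77 for dissociation stress.

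In macrophage-like cells, genes of Kupffer cells, the resident macrophages of the liver, were lower in the hKO library. Of 13 measured Kupffer genes 8 passed as lower and 0 as higher, with a median log2 ratio of −1.83, below all 10000 matched random lists (percentile 0). The scavenger receptor Marco had 272 UMIs in WT and 4 in hKO (log2 −5.88, −7.76 to −4.50), the apoptotic cell receptor Timd4 274 and 27 (−3.13), the hemoglobin receptor Cd163 140 and 23 (−2.40) and the folate receptor Folr2 1760 and 344 (−2.14). Marco, Timd4 and Cd163 lay under the floor of 50 CPM and are not among the 8. The chemokines Ccl8 (104 and 2444 UMIs, log2 4.77, 4.48 to 5.06) and Cxcl9 (log2 1.96) were higher in hKO. Macrophage-like cells lay mainly in clusters 10, 16 and 7 in WT and in clusters 8 and 7 in hKO. Clusters 8 and 10 had medians of 967.5 and 935.5 UMIs, and 778 hKO cells of the class formed a subcluster led by hepatocyte markers, against 12 in WT. Without subclusters led by another class the Kupffer median was −1.89, and within clusters 10 and 16 alone (1094 WT and 110 hKO cells outside those subclusters) it was −0.34 (−0.49 to −0.22), a comparison chosen after the data were seen. Clusters 10 and 16 were picked because genes of the same list led them.

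In all, 49 genes were higher and 58 lower in macrophage-like cells of hKO, with 54 and 5 more set aside as free RNA. The higher genes were 45.8% of those that passed, or 56.7% (76 higher, 58 lower) with abundant gene kinds left out of the total. The others highest in hKO were the calcium channel gene Cacna1a (log2 5.27), Gdpd3 (1.85), the collagenase Mmp13 (1.61), Lst1 (1.49), the heat shock gene Hspa1b (1.46), Cox17 (1.45), AY036118 (1.44) and the chemokine receptor Cxcr4 (1.43). Hspa1b was −1.09 with free RNA subtracted. Several of these genes were not particular to this class. Of the classes where each was measured, Cox17 was higher in 11 of 11, AY036118 in 10 of 11, Hspa1b in 8 of 9, and Gdpd3 and Lst1 each in 6 of 7. Lowest were the ficolin Fcna (−2.89), the lectin Cd207 (−2.70), Ccdc148 (−2.48), the potassium channel Kcnj16 (−2.41), the glucocorticoid-induced Fkbp5 (−2.37), Folr2, the complement genes C6 (−2.14) and Vsig4 (−2.14), Pcolce2 (−2.09) and Ctla2b (−1.90). Fcna, Cd207, Kcnj16, Folr2, C6 and Vsig4 also led clusters 10 or 16, and Ccl8, Lst1 and Mmp13 led cluster 8.

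Thinned to 1000 UMIs per cell, 27.6% (25.1 to 30.2) of WT and 6.96% (5.62 to 8.51) of hKO macrophage-like cells had a UMI of Clec4f, a Kupffer lectin. For Vsig4 the shares were 31.6% and 6.80%, for Timd4 3.66% and 0.316%, for the lipid receptor Trem2 19.4% and 12.7%, and for Gpnmb 9.76% and 5.30%. Thinning left out 449 WT and 456 hKO cells. The unthinned shares were 32.6% and 7.56% for Clec4f, 36.6% and 9.36% for Vsig4, 6.85% and 0.523% for Timd4, 33.7% and 26.5% for Trem2, and 15.1% and 9.42% for Gpnmb, at median depths of 2403 and 2113.5 UMIs. T-like cells, taken as background although they include a subcluster led by macrophage markers (74 WT and 306 hKO cells), gave 2.77% and 0.671% for Clec4f, 2.70% and 0.732% for Vsig4, 0.0711% and 0% for Timd4 (0 of 1640 cells, where 3 counts would be 0.183% of cells with a UMI), 2.20% and 1.46% for Trem2, and 0.640% and 0.610% for Gpnmb.

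Lipid-associated macrophage genes, named for cells that clear lipid in fatty tissue, had 3 of 16 lower and 0 higher (median −0.29, percentile 1.98): Gpnmb (−1.47), Spp1 (−1.18) and Trem2 (−1.03). Gpnmb, Spp1 and Trem2 also led subcluster 4, named lipid-associated, with 511 WT and 37 hKO cells, and the Kupffer subclusters held 966 and 51, so these list values follow in part the make-up of the class. Marco, Cd207 and Vsig4 were among the leading genes of subcluster 4 too. Cacna1a, Mmp13 and Ccl8, higher in hKO, were among those of subcluster 2, with 26 WT and 736 hKO cells. Spp1 reached 3.52 with free RNA subtracted. Interferon response genes had 1 of 19 higher and 2 lower (median −0.39, percentile 0.01; Cxcl9 1.96, Ifit3 −1.29). Chemokines had 2 of 18 higher and 1 lower (median 0.06, percentile 88.9), with Ccl8, Ccl12 (2.58), Cxcl1 (−2.48) and Cxcl9. Inflammatory macrophage genes had a median of 0.01 (percentile 73.9; Il12b −2.30) and alternative macrophage genes −0.30 (4.62), among them Retnla (26 UMIs in WT and 0 in hKO, at least 7.49-fold lower, but log2 0.96 at a mitochondrial limit of 10%). Medians were 0.39 for cholesterol synthesis (percentile 99.95; Sqle 1.30), which became −0.89 (Sqle −1.11) with free RNA subtracted, −0.32 for the unfolded protein response (0.94; Sdf2l1 −0.92, Manf −0.60) and −0.24 for dissociation stress (2.26; Ier3 −0.69). They were 0.24 for MHC class I presentation (98.8; Tap1 0.48, Psmb8 −0.44; median −0.054 with the libraries clustered separately), 0.14 for MHC class II presentation (92.2; Ciita 0.47, H2-Oa 0.36), 0.25 for inhibitory ligands and mediators (98.4; Cd276 1.64, Il10 −1.18) and −0.10 for costimulatory ligands (42.8; Tnfsf18 −0.94, Icosl 0.76). For metabolism they were 0.15 for fatty acid binding and uptake (93.1; Slc27a2 4.03, Slc27a5 2.31), 0.15 for lipid droplets (91.5; Hsd17b13 3.76, Dgat2 2.53), −0.20 for ferroptosis regulators (8.08; Slc7a11 1.16, −0.14 at resolution 2.0, and Hmox1 −1.02) and −0.22 for glycolysis and hypoxia (5.54; Ankrd37 −2.11, Adm −1.94). Proliferation stood at −0.02 (59.4; Birc5 0.80, Mcm3 −0.59). The free hepatocyte list stood at 1.51 (percentile 100; Mup20 4.52), so the higher hepatocyte-made genes above (Slc27a2, Slc27a5, Hsd17b13, Dgat2) moved with it.

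**Figure D4:**
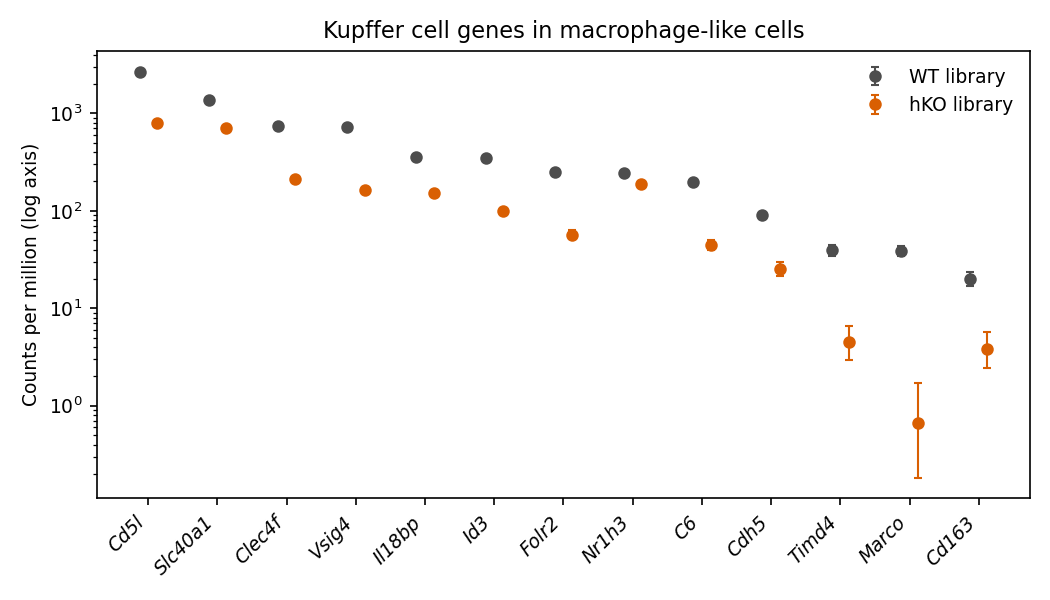
CPM (vertical log axis) of the 13 Kupffer cell genes (horizontal axis) in macrophage-like cells of the WT and hKO libraries, with exact Poisson 95% intervals as error bars. Marco stands at 39.0 in WT and 0.664 in hKO, and each of the 13 genes is lower in hKO.

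In T-like cells, a few effector genes were lower in the hKO library. The granzyme Gzma, a protease of killer cells, had 2424 UMIs in WT and 447 in hKO (log2 −2.83, −2.98 to −2.69). The integrin Itga1 of tissue-resident T cells (−2.28), the interleukin 12 receptor Il12rb2 (−2.53) and the inhibitory receptor Cd160 (−1.42) were lower too. Itga1, Il12rb2 and Cd160, with Atp8a2 and Trat1, led T-like subcluster 5, which held 280 WT (19.5%) and 28 hKO cells (1.68%), so their lower sums go with fewer cells of that subcluster. T activation and cytotoxicity genes had 2 of 21 lower and 0 higher (median −0.52, below all 10000 matched random lists), with Gzma, Il2 (61 and 18 UMIs, log2 −2.15, under the floor) and Fasl (−1.17). T exhaustion genes had 1 of 14 lower (median −0.28, percentile 6.73; Cd160, Lag3 −0.87), and 0 of 8 naive and memory genes passed (median −0.48, percentile 0.25; Klf2 −0.71, Il7r −0.64). Proliferation genes stood at 0.26 (percentile 99.97; Mcm5 0.73, Ccna2 0.64) with 0 of 16 past the rule, at −0.11 with a mitochondrial limit of 50% and at 3.32 with the libraries clustered separately.

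In all, 103 genes were higher and 25 lower in T-like cells of hKO, with 49 and 7 more set aside as free RNA. The higher genes were 80.5% of those that passed, or 68.9% (111 higher, 50 lower) with free RNA subtracted. The highest were Ccl8 (log2 5.70), Lst1 (2.36), Adgrl3 (2.02), Ms4a7 (2.01), S100a4, a calcium-binding protein of effector cells (2.00), Pf4 (1.97), Fcgr4 (1.78), Abi3bp (1.76), Hspa1b (1.75) and the histone gene Hist1h2ap (1.74). Ccl8, Lst1, Adgrl3, Ms4a7, Pf4 and Fcgr4 are macrophage or monocyte genes. A subcluster led by macrophage markers held 306 hKO and 74 WT T-like cells, and without subclusters led by another class Ccl8 stood at 5.69, Lst1 at 2.45 and Fcgr4 at 2.11. These values still include subcluster 7 (42 WT and 135 hKO cells), led by Adgrl3 and the macrophage receptor Mertk. The others lowest were the flippase Atp8a2 (−3.31), the transcription regulator Id3 (−2.38), Mmp16 (−1.57), Trat1 (−1.54), Dusp2 (−1.42) and the cyclin Ccnd3 (−1.38). The subcluster named gamma-delta by fixed markers held 13.4% (11.8 to 15.1) of hKO and 4.94% (3.88 to 6.20) of WT T-like cells, and the regulatory one 13.2% and 15.5%. Abi3bp was a leading gene of gamma-delta cluster 19.

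Thinned to 1000 UMIs, 9.39% of WT (7.91 to 11.0) and 12.0% of hKO T-like cells (10.4 to 13.6) had a UMI of Mki67 or Top2a, against a neutrophil-like background of 0.418% and 1.21%. Part of these cells lay in T-like subcluster 8, led by Plasma markers with Top2a and Mki67 (41 WT and 127 hKO cells). Without subclusters led by another class the shares were 6.54% (78 of 1193 cells) and 7.43% (87 of 1171 cells, 5.99 to 9.08), a difference not detectable at this depth, and the proliferation list median was 0.43. Macrophage-like cells, at 0.894% and 1.11%, did not stand clear of the background. For the checkpoint receptor Pdcd1 the T-like shares were 5.33% (4.22 to 6.64) and 5.61% (4.55 to 6.84), a difference not detectable at this depth, and for Ctla4 15.8% and 13.4%. Macrophage-like background was 0.0813% and 0.237% for Pdcd1 and 0.407% and 0.396% for Ctla4. Unthinned T-like shares were 17.2% and 23.9% for Mki67 or Top2a, 15.1% and 18.3% for Pdcd1, and 30.7% and 30.6% for Ctla4, with 30 WT and 31 hKO cells left out by thinning. In macrophage-like cells the ligand Cd274 was seen in 7.07% and 8.47% (unthinned 17.9% and 18.4%; hepatocyte-like background 0 of 222 cells, where 3 counts of the total would be 1.35% of cells with a UMI, and 0.501%). The costimulator Cd86 was seen in 23.3% and 17.3% (unthinned 41.2% and 34.7%; T-like background 4.69% and 4.82%). Other T-like medians were −0.43 for dissociation stress (percentile 0.05; Hspa1b, Ier3 −1.20; median 0.010 with the libraries clustered separately), −0.05 for interferon response (84.7; Cxcl9 1.00, Ifit3 −0.83; Cxcl9 −0.23 at a limit of 50% and −0.038 with free RNA subtracted), −0.06 for the unfolded protein response (80.3; Ddit3 −0.65, Sdf2l1 −0.40, or 0.25 with the libraries clustered separately) and 1.35 for the free hepatocyte list (percentile 100; Mup20 4.19, Apoa2 3.65).

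Endothelial-like cells differed in make-up: sinusoidal clusters 4 and 18 held 1321 of 1471 WT and 351 of 553 hKO cells, and cluster 24, led by Igfbp3 and Col4a1, 68 and 168. As a class, those of hKO held more of the retinol binding gene Rbp7 (log2 6.65), Igfbp3 (5.06) and the angiogenic peptide Apln (4.39), and less of Zbtb16 (−4.67), Pla2g7 (−2.59) and Csmd1 (−2.10). Angiogenesis and sinusoid genes had 3 of 14 higher and 1 lower (median 0.13, percentile 97.8; Apln, Aplnr 4.36), with a median of −0.10 at a mitochondrial limit of 10%, −0.08 with doublets kept and −0.19 with doublets removed only by the caller's own threshold. Endothelial medians were 0.60 for fatty acid binding and uptake (percentile 99.96; Slc27a5 3.70, Slc27a2 2.87), −0.07 for extracellular matrix (65.2; Fn1 1.43, Col4a1 1.27), −0.21 for dissociation stress (13.1; Ier3 −1.70, Nr4a1 1.25) and 1.38 for the free hepatocyte list (percentile 100; Mup20 4.17, Apoa2 3.58), which became −2.89 (Apoa2 −3.26) with free RNA subtracted. The hepatocyte-made Slc27a5 and Slc27a2 moved with the free hepatocyte list in the main setting. Over the alternatives the fatty acid median lay between 0.29 and 0.75. In neutrophil-like cells the granule genes Camp (470 and 2 UMIs, log2 −7.22), Ngp (832 and 7, −6.24) and Ltf (210 and 3, −5.47), made by immature neutrophils, were lower in hKO. Ugt2b34 (5.72), St18 (5.02) and Ccl8 (4.93) were higher there. The hepatocyte gene Ugt2b34 was higher in 11 of 11 classes, and Ccl8 led macrophage-like cluster 8 (41 WT and 795 hKO cells).

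Monocyte-like cells of hKO held more Ccl8 (log2 3.66, but −2.60 with free RNA subtracted), Hspa1b (1.98) and the zinc transporter Slc39a1 (1.91), and less Fkbp5 (−2.29), Spp1 (−1.89, but 0.40 at a mitochondrial limit of 10%) and Id3 (−1.71). Conventional dendritic-like cells held more Ccl8 (6.83), Lst1 (2.05, but −0.42 with free RNA subtracted) and Hspa1b (1.89), and less Id3 (−2.13), Spp1 (−1.98) and Fkbp5 (−1.95). Ccl8 also led macrophage-like cluster 8 (41 WT and 795 hKO cells), and Spp1 led unnamed cluster 25 (200 and 34). MHC class II genes, which present antigen to T cells, had medians of −0.50 in monocyte-like (percentile 0.13; H2-DMb1 −0.90, Cd74 −0.78), −0.49 in conventional dendritic-like (0.10; H2-DMb1 −0.81, Cd74 −0.68) and −0.48 in B-like cells (0.08; Cd74 −0.69, H2-Eb1 −0.66), with 0 members past the rule. With the libraries clustered separately, the monocyte-like median was 0.90, Cd74 0.57 and H2-DMb1 0.0088. Costimulatory ligands stood at −0.38, −0.30 and −0.13 in these 3 classes (percentiles 1.62, 11.9 and 63.2), with Cd48 at −0.47 in monocyte-like cells, Tnfsf9 at −0.71 in conventional dendritic-like cells and Cd80 at −1.60 in B-like cells. Inhibitory ligands and mediators stood at −0.06 in monocyte-like (percentile 41.9; Cd276 1.72) and 0.07 in conventional dendritic-like cells (95.5; Pdcd1lg2 0.67, Cd274 0.61). Other monocyte-like medians were −0.09 for inflammatory macrophage genes (61.1; Il12b −1.74, Il6 1.72), −0.30 for alternative macrophage genes (4.14; Ccl24 −3.08, Ccl17 2.56) and −0.14 for chemokines (30.5; Ccl8, Ccl24). Il12b became 2.45 and Ccl17 −1.36 at a limit of 50%, and Il12b 1.57 with the libraries clustered separately.

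Plasmacytoid dendritic-like cells of hKO held more Hspa1b (log2 2.92), Hspa1a (1.86) and the sterol enzyme Sqle (1.74), and less of the cholesterol exporter Abcg1 (−2.55), Dst (−2.43) and Mri1 (−1.57). NK or innate lymphoid-like cells held more Pigr (4.56), Romo1 (2.31, but higher in 9 of the 10 classes where measured) and Fam169b (2.29, −0.33 with the libraries clustered separately), and less Aff2 (−2.83), Chl1 (−1.69) and Dnajc9 (−1.52). Their T activation and cytotoxicity median was −0.36 (percentile 0.95; Gzmk −1.37, Klrg1 −0.88), with 0 of 18 past the rule, and 0.0066 with the libraries clustered separately. In B-like cells, which lay in cluster 3 in WT and cluster 5 in hKO, the hepatocyte genes Orm2 (6.92), Ugt2b1 (6.09) and Ugt2b34 (5.90) were higher. Fkbp5 (−1.52), the phosphatase Ptpn22 (−1.31) and Id3 (−1.22, but 4.39 with free RNA subtracted) were lower there, and the free hepatocyte list stood at 1.88 (percentile 100; Mup20 4.41, Apoa2 4.24). Erythroid-like cells held more of the hepatocyte genes Cyp2a5 (8.76, 6.26 to 14.07), Cyp2f2 (7.25) and Ugt2b34 (7.08), and less Ankrd12 (−4.35), Aopep (−4.23, but 0.70 with free RNA subtracted) and Ptprcap (−4.09, but 2.68 at resolution 2.0).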

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

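All tests in this part were chosen after the results they weigh were seen. Signals in barcodes and cells that no comparison uses come first. Barcodes over the mitochondrial limit, 6864 in hKO and 2645 in WT, held 5.28% of their UMIs from the free hepatocyte list in hKO and 2.18% in WT. Barcodes with under 200 genes, 593 in hKO and 2224 in WT, held 1.44% from that list in hKO and 0.595% in WT, and 58.8% and 80.8% hemoglobin. Unnamed cluster 25, with cholangiocyte and hepatocyte markers and led by Spp1, held Fabp5 at 50.1 CPM (counts per 1000000 UMIs) in hKO (exact Poisson interval 30.6 to 77.4, 20 UMIs in 34 cells) and 16.3 in WT (12.6 to 20.8, 65 UMIs in 200 cells).

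Kupffer genes were lower in macrophage-like cells of the hKO library, with a list median log2 ratio of −1.83. Removal of damaged Kupffer cells by the mitochondrial limit is argued against, since the median was −2.10 at a limit of 50%. Fewer Kupffer cells, each at an unchanged level, cannot be told apart from lower levels per cell: in the Kupffer-led clusters 10 and 16 (1094 WT and 110 hKO cells) the list had a median of −0.34 (−0.49 to −0.22), with Clec4f at 0.16 and Slc40a1 at 0.01, and Marco at −3.56 (−5.45 to −2.19). That interval lay on the lower side throughout, but not wholly past the bound set for lower levels. The clusters were also picked because genes of this list led them, so the list cannot decide the question there. A smaller part of sinusoidal liver in the hKO pool may contribute, since the share of sinusoidal endothelial-like cells had a log2 ratio of −2.05 (−2.21 to −1.88; 14.0% of WT and 3.37% of hKO cells) and that of other endothelial-like cells 0.29 (−0.01 to 0.59). The knockout itself stays open and untested, with 1 pool per group.

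Hepatocyte-like cells were more frequent in the hKO library and lay in other clusters than in WT. Droplets of free RNA as the make-up of hKO cluster 9 (median 1379 UMIs, against 1300 in WT cluster 21) are argued against, since it held 1.57 hemoglobin UMIs per 100 free hepatocyte list UMIs, against 11.3 in T-like cells, the lowest of the other classes. The mitochondrial limit may set much of the share, because among cells up to 10% its log2 ratio was 0.39 (0.06 to 0.71) with the same clusters in place of 1.52. Which WT cells are called hepatocyte-like bears on it too: clustered again at that limit it was −0.11, and without a change of limit 1.11 at resolution 2.0, 0.94 with doublets kept and 0.91 with stricter cell minimums. That cluster alone carrying the higher NRF2 targets is argued against by a median of 1.40 for that list without it. Tumors that differ between the pools, by the knockout or by chance, stay open and were not tested.

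Glucocorticoid-responsive genes were lower in many classes of the hKO library, Fkbp5 in 11 of 11 (log2 from −4.23, interval −9.57 to −1.69 with 1 hKO UMI, in erythroid-like to −0.61 in T-like cells) and Tsc22d3 with an interval below 0 in 10 of 11 (−1.51 to 0.03), while Mt1, which also answers to these hormones, was higher in 9 of 11 and lower in 2. The scaling to the class total is argued against, since a list written after the data were seen, without Fkbp5 and Zbtb16 (15 genes), lay under percentile 2.5 of matched random lists in 6 of 11 classes. Few of its genes passed the rule of size as lower: 6 in hepatocyte-like, 2 in conventional dendritic-like, 1 each in neutrophil-like and erythroid-like cells, and 0 in the other classes. In macrophage-like, monocyte-like, neutrophil-like and T-like cells 1 passed as higher. Free RNA of 1 source is argued against, because Fkbp5 UMIs per 100 free hepatocyte list UMIs ranged 8.22-fold over the WT classes outside hepatocytes, from 1.52 in erythroid-like to 12.5 in endothelial-like cells. Tumors taken at different times of day cannot be told apart from the groups: a clock list of 15 genes lay outside the middle 95% of matched random lists in 0 of 9 classes, and the hours of collection are not given in the sources used here. A difference in stress hormone at collection, or the knockout, was not tested.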

How the results depend on the processing

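The 17 alternatives were chosen before the data were examined, and the 3 marked as added after the data were seen. Over these alternatives the log2 ratio of the share kept its sign for endothelial-like (−1.73 to −1.30) and plasmacytoid dendritic-like cells (1.31 to 1.62), and Fabp5 in hepatocyte-like cells (−3.59 to −1.02) and the Kupffer list in macrophage-like cells (−2.65 to −1.53) stayed below 0. At a mitochondrial limit of 50% hepatocyte-like genes were not compared, since 64 WT cells were left in the class. Of 2954 values for 241 genes 36 changed sign from a value whose interval excluded 0. Of 847 values for 63 results on lists 16 changed sign, counted by another rule. There the main median had to lie outside the middle range of matched random lists used above for the clock list. Sign changes of lists within that range were not counted and are not listed below. Over the alternatives, for example, the proliferation list in hepatocyte-like cells (main median −0.66) reached 1.21. The MHC class I presentation list there (0.26) fell to −0.72, and the alternative macrophage list in monocyte-like cells (−0.30) reached 0.86. Without a counted change of sign, 622 values for genes and 278 for lists lay outside their main interval. Of 135 values for 31 shares, 7 changed sign from a value whose interval excluded 0, in 4 shares. The values that follow are the counted changes of sign. For shares, counts, Fabp5 and the Kupffer list, those outside their interval or over 1.5 times away follow too. For each of them the cause was not tested, except that a higher floor or size requirement leaves fewer genes by construction. With a mitochondrial limit of 10%, the log2 ratio of the share was −1.73 for endothelial-like, −0.11 for hepatocyte-like, 0.78 for macrophage-like, −0.83 for B-like, 0.54 for conventional dendritic-like, 0.91 for monocyte-like and −0.97 for NK or innate lymphoid-like cells. The genes higher in hKO were 382 in hepatocyte-like, 75 in macrophage-like and 189 in T-like cells, and lower ones 110 in macrophage-like and 38 in T-like cells. Log2 values were Ccnb2 0.72, Cdh2 −0.40, Fabp5 −1.26, Hspb1 −0.12, Hyou1 −0.072, Por −0.072, the cholesterol synthesis list −0.34 and the unfolded protein response list −0.14 in hepatocyte-like cells, Fabp5 1.02, Retnla 0.96 (a bound in the report, with 0 hKO UMIs) and the Kupffer cell list −2.65 in macrophage-like cells, Spp1 0.40 in monocyte-like cells, and the angiogenesis and sinusoid list −0.10 in endothelial-like cells. With a limit of 50%, the log2 ratio of the share was −0.18 for conventional dendritic-like, 5.29 for hepatocyte-like, 0.11 for macrophage-like, 1.31 for plasmacytoid dendritic-like, 0.19 for stellate or fibroblast-like, −0.33 for T-like, −0.38 for B-like, −2.94 for mast or basophil-like, 0.22 for monocyte-like, −1.11 for NK or innate lymphoid-like and −1.34 for neutrophil-like cells. Ratios on the log2 scale were Ccl17 −1.36 and Il12b 2.45 in monocyte-like cells, Cxcl9 −0.23, Fabp5 −0.10 and the proliferation list −0.11 in T-like cells, and the Kupffer cell list −2.10 in macrophage-like cells. With at least 500 genes and 1000 UMIs per cell, the log2 ratio of the share was −1.32 for endothelial-like, 0.91 for hepatocyte-like, −0.24 for macrophage-like, −0.28 for B-like, −1.86 for erythroid-like and −0.89 for NK or innate lymphoid-like cells. Genes higher in hKO numbered 359 and lower ones 1495 in hepatocyte-like cells. Log2 ratios were Ccnb2 0.10, Cdh2 −0.027, Fabp5 −1.02, Hspb1 −0.32 and the cholesterol synthesis list −0.31 in hepatocyte-like cells. With doublet calls kept, the log2 ratio of the share was −1.38 for endothelial-like and 0.94 for hepatocyte-like cells. The genes higher in hKO were 337 and lower ones 1466 in hepatocyte-like cells. Log2 values were Cdh2 −0.016, Creld2 −0.53, Fabp5 −1.31, Hspb1 −0.40, Hyou1 −0.047, the cholesterol synthesis list −0.27 and the unfolded protein response list −0.66 in hepatocyte-like cells, and the angiogenesis and sinusoid list −0.082 in endothelial-like cells. At Leiden resolution 0.5, the log2 ratio of the share was −0.23 for macrophage-like and −0.88 for NK or innate lymphoid-like cells. At Leiden resolution 2.0, the log2 ratio of the share was 1.11 for hepatocyte-like cells. Genes higher in hKO numbered 344 and lower ones 1482 in hepatocyte-like cells. Ratios on the log2 scale were Ptprcap 2.68 in erythroid-like cells, Cdh2 −0.05, Fabp5 −1.34, Hspb1 −0.40 and the cholesterol synthesis list −0.30 in hepatocyte-like cells, and Slc7a11 −0.14 in macrophage-like cells. With the libraries clustered separately, the log2 ratio of the share was −0.42 for macrophage-like, 0.25 for T-like, 1.23 for monocyte-like and −1.15 for NK or innate lymphoid-like cells. The genes higher in hKO were 221 and lower ones 45 in T-like cells. Log2 ratios were Cd74 0.57, H2-DMb1 0.0088, Il12b 1.57 and the MHC class II presentation list 0.90 in monocyte-like cells, Fam169b −0.33 and the T activation and cytotoxicity list 0.0066 in NK or innate lymphoid-like cells, Sdf2l1 0.25 and the dissociation stress list 0.010 in T-like cells, and the MHC class I presentation list −0.054 and the Kupffer cell list −1.53 in macrophage-like cells. With doublets removed only by the caller's own threshold (added), the log2 ratio of the share was −1.30 for endothelial-like and 0.59 for macrophage-like cells. The angiogenesis and sinusoid list stood at −0.19 in endothelial-like cells. With mitochondrial, ribosomal-protein and free hepatocyte genes left out of the total, genes higher in hKO numbered 870 in hepatocyte-like and 76 in macrophage-like cells. The Kupffer cell list stood at −1.74 in macrophage-like cells. With median scaling, genes higher in hKO numbered 892 in hepatocyte-like and 156 in T-like cells, and lower ones 466 in hepatocyte-like cells. With the mean over cells, log2 ratios were Fabp5 −3.44 in hepatocyte-like cells and the Kupffer cell list −2.43 in macrophage-like cells. With free RNA subtracted, by a profile of the kept cells that also holds their own RNA, genes lower in hKO numbered 50 in T-like cells. Log2 values were Id3 4.39 in B-like cells, Lst1 −0.42 in conventional dendritic-like cells, Apoa2 −3.26 and the free hepatocyte RNA list −2.89 in endothelial-like cells, Aopep 0.70 in erythroid-like cells, Fabp5 −3.59 in hepatocyte-like cells, Hspa1b −1.09, Spp1 3.52, Sqle −1.11 and the cholesterol synthesis list −0.89 in macrophage-like cells, Ccl8 −2.60 in monocyte-like cells, and Cxcl9 −0.038 and Fabp5 2.34 in T-like cells. At a floor of 20 CPM, genes higher in hKO numbered 1020 in hepatocyte-like and 78 in macrophage-like cells, and lower ones 1440 in hepatocyte-like, 93 in macrophage-like and 55 in T-like cells. At a floor of 200 CPM, genes higher in hKO numbered 204 in hepatocyte-like, 19 in macrophage-like and 45 in T-like cells, and lower ones 248 in hepatocyte-like, 23 in macrophage-like and 10 in T-like cells. With a log2 ratio of at least 1.5 required, genes higher in hKO numbered 5 in macrophage-like and 21 in T-like cells, and lower ones 406 in hepatocyte-like, 27 in macrophage-like and 7 in T-like cells. As a share of cells that are not hepatocyte-like, the log2 ratio of the share was 0.0052 for macrophage-like, −0.047 for B-like and 0.19 for T-like cells. Without subclusters led by another class (added), genes lower in hKO numbered 41 in T-like cells. Without hepatocyte-like cluster 9, led by Cyp2a5, Ugt2b5 and Mup20 (added), genes lower in hKO numbered 462 in hepatocyte-like cells. List members with at least 100 UMIs and thinning to 500 UMIs made none of the counted changes of sign. At 500 UMIs the log2 ratio of the share of cells was −0.63 for Cd274 in monocyte-like cells (−0.18 at 1000 UMIs) and −0.50 for Cd86 in conventional dendritic-like cells (0.08 at 1000 UMIs, with an interval that includes 0). No paired analysis was possible because each group is 1 pooled library. Depth limits ratios that rest on few UMIs: the interval of Slc7a11 in hepatocyte-like cells, with 1 WT UMI, ran from 4.77 to 12.56, and Fabp5 in erythroid-like cells, with 6 and 0 UMIs, has no ratio. The Slc7a11 ratio was also much smaller under the settings named for Fabp5, where WT hepatocyte-like cells held more UMIs.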

Other observations

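The counts of classes and the cells compared in this part were chosen after the data were seen. Some genes differed the same way in most classes. Of 3081 genes measured in at least 6 of the 11 classes, 94 were higher in hKO and 5 lower in at least 6 classes. These counts omit the gene kinds that the naming rule leaves out. The lower ones were Id3, a repressor of helix-loop-helix transcription factors (9 of 10 classes, median log2 −2.13), Jchain, which joins antibody units (9 of 9, −5.73), Fkbp5 (8 of 10, −1.52), the cyclin Ccnd3 (8 of 11, −1.09) and the ubiquitin gene Ubb (6 of 11, −1.17). Plasma-like cells, the makers of Jchain, numbered 61 in WT and 3 in hKO, but 74 and 46 with doublets kept. Of the kinds left out of the counts, the immunoglobulin genes Igkc (11 of 11 classes) and Igha (8 of 8) were lower in hKO too. So were hemoglobin genes, such as Hbb-bs (9 of 11). Among the genes higher in 11 of 11 classes were hepatocyte transcripts such as Cyp2a5 (median log2 7.54), C3 (3.80) and Mup20 (4.42). Other genes were also higher in 8 or more classes. Among them were the respiratory-chain genes Cox6c (1.48), Ndufa1 (1.30), Uqcr10 (1.24) and Uqcr11 (1.42) and the mitochondrial gene mt-Nd3 (1.88). The ribosomal-protein genes Rpl37a (1.35) and Rpl41 (1.29) were among them too, as were Romo1 (1.49), Snrpg (1.21), Tomm7 (1.38) and Polr2k (1.23). No gene list was set for them, and RNA or library quality was not tested as a cause.

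Sinusoidal endothelial-like cells, the lining of liver capillaries, were 3.37% of hKO and 14.0% of WT cells, while other endothelial-like cells were 1.94% and 1.59%. In the Kupffer-led macrophage-like clusters, 110 cells in hKO and 1094 in WT, Marco stood at a log2 ratio of −3.56 (−5.45 to −2.19), Timd4 at −1.25, Vsig4 at −0.29 and Cd5l at −0.17, and Nr1h3 at 0.21 (−0.0099 to 0.42). The Fabp5 level of cluster 21, the WT hepatocyte-like cells, was 104.7 CPM, and those of the hKO cells of clusters 9 and 22 were 8.87 and 17.5 (12.3 to 24.2). The 21 WT cells of cluster 22 held 23.2 (0.588 to 129.5, 1 UMI), so no difference was detectable at this depth within that cluster. No hypothesis was tested on these values here.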
